A study of Homo sapiens with 6 samples.

How the data were processed

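RNA was sequenced from Raji cells, an established human cell line derived from a Burkitt's lymphoma of germinal centre origin. Per the labels' protocols, the cells were infected for 5 days with lentivirus carrying either human IRF4 cDNA or no insert, then selected for 7 days in puromycin at 3 µg/ml. RNA was isolated with a column kit and made into stranded, poly(A)-selected Illumina libraries. The labels name 3 libraries per group, called control and IRF4-overexpressing here. They do not say whether the replicates were separate infections or cultures. The p-values therefore measure the spread between these libraries, which may be technical.

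The deposited table holds raw read counts per gene, with 1 column per library and no pooling or scaling. That these are counts follows from the values, which are whole numbers whose totals differ between columns. The control columns are called WT in the table, while per the labels the control received the empty vector. A further deposited column gives 1 width per gene, in bases by the column's header and values, and entered the length checks alone. Per the submitters' processing notes, the genome builds were mm9 and hg19, and these human samples were taken to belong to the latter. The aligner, the counting tool, the annotation and the strand setting were not given in the sources used here. Reads of overlapping, antisense or near-identical genes could therefore have been assigned in ways that cannot be checked here.

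The table has 23459 rows of Entrez gene identifiers, of which 23308 matched a symbol in the reference gene table of GRCh38.p14. The remaining 151 held 0.122% of the counts and stayed in the tests under their identifiers. No coordinates are given, because the reference is of another build. A count of 0 in every library was found for 6097 genes. The totals were 41510523, 27681979 and 37949438 counts in control replicates 1, 2 and 3, and 33588248, 35920302 and 46210702 in IRF4-overexpressing replicates 1, 2 and 3. Counting intervals are exact at the 95% level, the floor for a group at 0 is 3 counts over the group, and both cover counting error only.

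Every choice in this paragraph was made before the data were examined. The groups were compared with edgeR 4.0.16 (R 4.3.3), with TMM scaling, the filterByExpr filter, a group-only design and the two-sided quasi-likelihood F-test over the 12079 genes kept. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called changed. CPM values, counts relative to the library size, used library sizes scaled by TMM. Standard errors (SE) of log2 fold changes were derived from the F statistic, as the absolute log2 fold change divided by its square root. Of 25 gene lists, with 577 of 607 written members found in the table, 21 had at least 5 tested members. These were tested with camera (limma 3.58.1) at a preset correlation of 0.01, adjusted over the lists. IRF4 was in no list, and some genes were in more than 1. Genes named in the text were IRF4, 14 study genes (octamer factors, their coactivator, and germinal centre or plasma cell regulators), and the 12 largest rises and 12 largest falls. The last 2 sets required an adjusted p under 0.05, a mean CPM of at least 5, no overlap between groups, and no symbol of a non-coding RNA, ribosomal pseudogene or uncharacterised locus. Also named were the 4 members with the smallest p in the direction of each called list, and the 2 with the smallest p of each other list. Some genes that this rule names are not reported here.

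The alternatives were median-ratio size factors, library sizes alone, no filter, a filter of at least 1 CPM in 3 libraries, DESeq2 1.42.0, limma-voom, the replicate number as a block, leaving out each library, and leaving IRF4 out of the counts. Further ones were camera with an estimated correlation, fry, and glmTreat against a fold change of 1.5. After the data were examined, a term for a split of the libraries, 1 surrogate variable (sva 3.50.0), and offsets for GC content and gene length were added. GC content came from the longest annotated transcript and was known for 97.6% of the genes tested. Figures were drawn with matplotlib 3.10.9.

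Before use, the test was run on simulated counts for the 12079 genes of this comparison, with 200 genes changed. It recovered 9.1% of genes changed 1.5-fold, 68.7% of those changed 2-fold and 97.0% of those changed 4-fold, and 9 of its 139 calls were false. A shift planted on 1 list was found, and 0 of the other 20 lists were called. The simulated genes varied independently of each other, without the split of the libraries seen in the real counts. The simulation therefore does not show how often lists are called falsely in these libraries. All replicate pairs differed by more than sampling noise, with a chi-square per gene of 6.6 to 199.9, so no pair was treated as copies of 1 library. This does not show that they came from separate cultures.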

Results

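Gene expression was measured by RNA-seq in 3 control and 3 IRF4-overexpressing libraries of Raji cells, with 27681979 to 46210702 counts per library. IRF4 is a transcription factor of activated B cells and plasma cells. The series concerns the germinal centre transcription program, and its human part asks how raised IRF4 changes expression in a germinal centre-derived lymphoma line.

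IRF4 itself (Entrez gene 3662) was at 1.26 ± 0.203 CPM in control libraries (SD, n = 3) and at 132 ± 15.8 CPM in IRF4-overexpressing libraries (SD, n = 3). The counts were 41, 37 and 50 against 5162, 4462 and 6054. Its log2 fold change was 6.72 (SE 0.18, edgeR adjusted p = 3.79e-05). Reads from the introduced cDNA and the cell's own gene were counted together.

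With IRF4 raised, genes of the interferon response rose together, and far more genes rose than fell. Besides IRF4, among called genes with a mean of at least 5 CPM and no overlap between the groups, the largest rises were in IFI27 (106-fold) and IFI44L (66.0-fold), both induced by type I interferon. The IFI27 value rests on 14, 4 and 5 control counts, and its log2 fold change of 6.73 was 6.47 to 7.34 without single libraries. The chemokine genes CXCL9 (10.0-fold) and CXCL10 (8.87-fold) rose as well. The largest fall among them was in UBASH3B, encoding a phosphatase that restrains receptor signalling, to 0.44 of its control level. By edgeR's quasi-likelihood test, 360 genes were higher and 22 lower of the 12079 tested, and 250 and 3 of these changed at least 2-fold. Of the higher genes, 169 had a mean of at most 3 CPM, among them CD28 and ITGAM. Weak genes as a class were higher too: the 5429 genes with a mean of at most 0.3 CPM summed to 231 ± 9.06 CPM in control and 370.1 ± 10.7 CPM in IRF4-overexpressing libraries (SD, n = 3 each).

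That imbalance among all calls depended on the model. Higher genes made up 94.2% of calls, against 76.7% with DESeq2 (577 higher, 175 lower), 79.7% with GC and length offsets (545 and 139), 64.6% with a term for a split of the libraries (709 and 389) and 38.7% with a surrogate variable (1353 and 2147). Scaling by library sizes alone moved the median log2 fold change of all genes from 0.01 to 0.10 and gave 503 higher and 13 lower genes. Higher genes made up 97.5% of those calls, 94.3% with median-ratio size factors and 93.9% with limma-voom. Of changes of at least 2-fold, higher and lower ones numbered 302 and 11 with DESeq2, and 284 and 4 with the offsets. With the split term they numbered 315 and 9, and with the surrogate variable 375 and 15. The offsets, the split term and the surrogate variable were added after the data were examined. Leaving out IRF4-overexpressing replicate 1 gave 2436 higher and 3071 lower genes, with 422 and 661 at least 2-fold. Leaving out any other library gave 120 to 156 higher and 3 lower.

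The libraries differed within groups along a shared axis. Control replicate 1 with IRF4-overexpressing replicates 2 and 3 lay on one side, and the remaining 3 libraries on the other. This axis held 74.3% of the variance of log2 CPM around the group means. Without IRF4-overexpressing replicate 1, both remaining libraries of its group share a side with control replicate 1, opposite control replicates 2 and 3. Values of that fit, here and below, therefore mix the group with the axis. RPS16, a ribosomal protein gene, was at 153, 563 and 699 CPM in control replicates 1, 2 and 3, and at 626, 27.6 and 39.0 CPM in the IRF4-overexpressing ones. Within the side with 1 control library, 2193 genes were higher and 2999 lower, and within the side with 1 IRF4-overexpressing library, 661 and 528. Each side has 1 group with a single library, which the fit assumes to vary like the others. The sides and the surrogate variable were read from these counts, so p-values from fits that use either are too small. The offsets were fitted to the same counts. The numbers of genes within the sides are no test of agreement between sides.

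**Figure D1:**
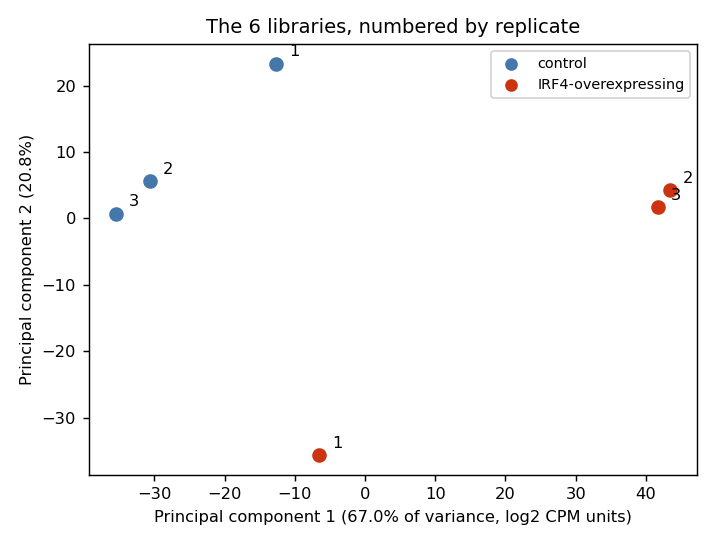
Scores of the 6 libraries on the 2 leading principal components of log2 CPM, which held 67.0% and 20.8% of the variance; each point is a library, coloured by group and numbered by replicate. IRF4-overexpressing replicate 1 lies apart from replicates 2 and 3.

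Of 32 tested interferon-stimulated genes, 27 rose and 0 fell, with a median log2 fold change of 1.84 (camera adjusted p = 1.37e-120). With an estimated correlation the camera adjusted p was 0.00603. Adjusted over the list alone, 28 rose, and without single libraries 23 to 29 rose. IFI44L rose from 2.21 ± 0.33 to 147 ± 21.7 CPM (SD, n = 3 each; log2 fold change 6.05, SE 0.19, edgeR adjusted p = 5.23e-05). SAMD9L, an antiviral gene, had a log2 fold change of 3.18 (SE 0.14, edgeR adjusted p = 2.27e-04). IFIT1, IFIT2 and IFIT3, whose products bind foreign RNA or assist in this, rose 17.8-fold, 5.87-fold and 9.48-fold, IFI44 rose 11.1-fold and IFI6 7.71-fold. Within the 2 sides of the library axis, the list's median log2 fold change was 1.86 and 1.62.

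**Figure D2:**
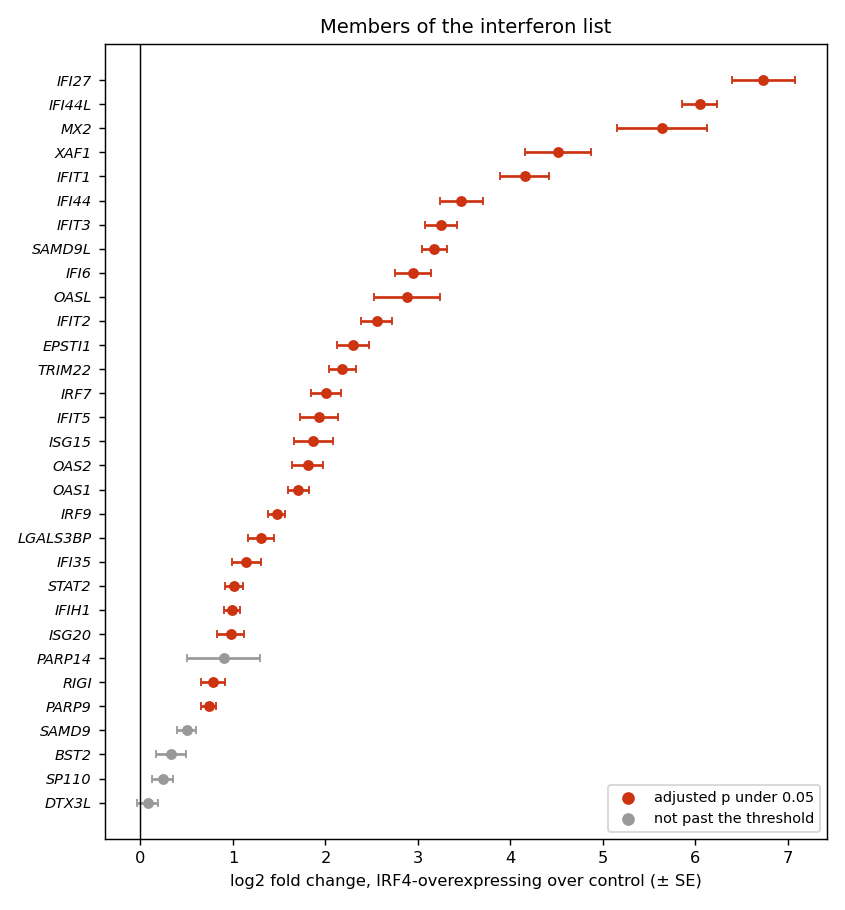
Log2 fold change of IRF4-overexpressing over control libraries, with its SE (n = 3 per group), for 31 of the 32 tested interferon-stimulated genes; red points had an edgeR adjusted p under 0.05. All 31 values drawn lie above 0, and 26 of them passed the test.

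Genes of the NF-kB and CD40 response also rose, 8 of 30 tested with 0 lower (21 when adjusted over the list alone). Without IRF4-overexpressing replicate 1 it was 20 higher and 2 lower, and without any other library 2 to 5 higher. The camera adjusted p was 2.93e-13, and 0.0103 with an estimated correlation. EBI3, a cytokine subunit gene, rose 2.91-fold, CCR7, the receptor that guides cells to T cell zones, 3.42-fold, the activation marker CD83 1.83-fold and the death receptor gene FAS 1.70-fold. In the MHC class I list, 5 of 15 genes rose (10 adjusted over the list alone; camera adjusted p = 8.99e-06, and 0.0465 with an estimated correlation). Without IRF4-overexpressing replicate 1 it was 10 higher and 1 lower, and without any other library 1 to 3 higher. The 5 included HLA-F (2.40-fold), HLA-B (1.53-fold), the peptide transporter gene TAP1 (1.66-fold) and NLRC5 (1.58-fold), an activator of class I genes. HLA genes are near-identical in part, so their single values are uncertain. Without single libraries, CD83, FAS, HLA-B, TAP1 and NLRC5 lost their calls in at least 1 fit. HLA-B and TAP1 also lost theirs with GC and length offsets (edgeR adjusted p = 0.0706 and 0.0704).

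Lists of migration, MHC class II, BCL2 family, plasma cell and myeloid genes were called higher with the preset correlation, but not with an estimated one. The estimates were -0.036, -0.057, -0.030 and -0.140 for migration, BCL2, plasma cell and myeloid genes, below the preset 0.01. For class II the estimate was 0.092. Outside class II, correlation between members therefore does not explain the lost call. By fry, the migration, class II, BCL2, plasma cell and myeloid lists were all called higher (fry adjusted p = 2.18e-04, 9.92e-04, 0.00194, 0.00157 and 2.18e-04). Other splits of the libraries into 3 and 3 also called 4 to 10 lists with the preset correlation. In the migration list, 4 of 15 rose, including CCR7, CD69 (2.39-fold) and GPR183 (2.03-fold), and the camera adjusted p = 0.0889 with an estimated correlation (9.37e-04 preset; 6 rose and 1 fell adjusted over the list alone). In the class II list, 1 of 17 rose, HLA-DQA1 (1.47-fold), against 11 adjusted over the list alone (camera adjusted p = 0.0027 preset, and 0.164 with an estimated correlation). HLA-DOB, HLA-DMB and HLA-DRB1 had log2 fold changes of 0.51, 0.45 and 0.41, which did not pass. In the BCL2 list, 3 of 15 rose, also when adjusted over the list alone (camera adjusted p = 0.0166 preset, 0.077 without control replicate 1, and 0.114 with an estimated correlation). These were BCL2 (2.02-fold) and BCL2A1 (3.07-fold), which block apoptosis, and BBC3 (1.73-fold), which promotes it, while BIK had a log2 fold change of 0.55. The myeloid list had 6 tested genes, of which ITGAM (3.78-fold) and MS4A7 (2.26-fold) rose, and 3 rose and 1 fell adjusted over the list alone (camera adjusted p = 0.00155 preset, and 0.0954 with an estimated correlation). Without single libraries, higher genes numbered 2 to 7 in the migration list, 0 to 13 in the class II list, 1 to 7 in the BCL2 list and 2 to 3 in the myeloid list, and lower ones 0 to 3, 0 to 3, 0 to 3 and 0 to 1. ITGAM reached 2.48 CPM. CSF1R and CD68 had log2 fold changes of 2.38 and 0.20 and did not pass. CSF1R was at 4.07, 1.22 and 1.39 CPM in IRF4-overexpressing replicates 1, 2 and 3, and without replicate 1 its log2 fold change was 1.63 and passed (edgeR adjusted p = 0.00198), as it did by DESeq2 (4.41e-04) and with the offsets, the axis term and the surrogate variable (0.0445, 0.00244 and 5.6e-06). Beside these rises, the 58 markers of myeloid, T and NK, epithelial, mesenchymal and kidney cells summed to 65.5 ± 4.66 CPM in control and 74.1 ± 5.07 CPM in IRF4-overexpressing libraries (SD, n = 3 each).

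Of 19 tested plasma cell genes, 3 rose and 0 fell (4 and 1 adjusted over the list alone; 1 to 11 and 0 to 4 without single libraries), with a camera adjusted p of 0.0166 preset and 0.114 with an estimated correlation. CD28, a costimulatory receptor gene, had 0 counts in all 3 control libraries and 205 in IRF4-overexpressing ones, at least 59.1-fold higher against a floor of 3 counts over the control group. SLAMF7 rose 4.31-fold and the kinase gene PIM2 1.63-fold. CD38 had a log2 fold change of 0.32 (SE 0.09, edgeR adjusted p = 0.131). PRDM1, the repressor that drives plasma cell differentiation, was at 2.14 ± 0.0464 and 1.28 ± 0.189 CPM (SD, n = 3 each; log2 fold change -0.75, edgeR adjusted p = 0.07; called lower by DESeq2, adjusted p = 0.034, with the offsets, the axis term and the surrogate variable, 0.0447, 0.0455 and 0.0152, and without IRF4-overexpressing replicate 1, 0.00643), and XBP1, a secretory regulator, had a log2 fold change of 0.24. Without single libraries, SLAMF7 and PIM2 lost their calls in at least 1 fit, as did CD69, GPR183, HLA-DQA1, BCL2A1 and BBC3. The plasma cell list lost its call without control replicate 1 (camera adjusted p = 0.115), with GC and length offsets (camera adjusted p = 0.117) and with the replicate block (camera adjusted p = 0.0512).

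Of 22 tested germinal centre genes, 2 rose and 0 fell, also when adjusted over the list alone (0 to 5 and 0 to 10 without single libraries), and the list was not called (camera adjusted p = 0.873). Among them, SUGCT rose 1.94-fold and lost its call in at least 1 fit without a library. Of the 14 study genes, 1 passed edgeR's test, and 0 passed without control replicate 2 or 3 or IRF4-overexpressing replicate 2 or 3. Log2 fold changes were -0.36 for BCL6, the repressor that maintains germinal centre B cells (edgeR adjusted p = 0.265), -0.52 for PAX5, 0.48 for BACH2, -0.44 for MEF2B, -0.19 for S1PR2 and -0.19 for MYC. The octamer factor genes POU2F1 and POU2F2 had -0.57 and -0.67 (SE 0.20 and 0.49) and their coactivator gene POU2AF1 -0.13, while SPIB had 0.23 and CIITA -0.05. Without single libraries, POU2F2 ran from -1.46 to -0.36. POU2F2 and CIITA varied with the library axis, at 123, 37.4 and 40.1 CPM and at 230.0, 84.7 and 91.7 CPM in IRF4-overexpressing replicates 1, 2 and 3. Without IRF4-overexpressing replicate 1, a fit that mixes the group with the library axis, all 14 study genes passed.

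**Figure D3:**
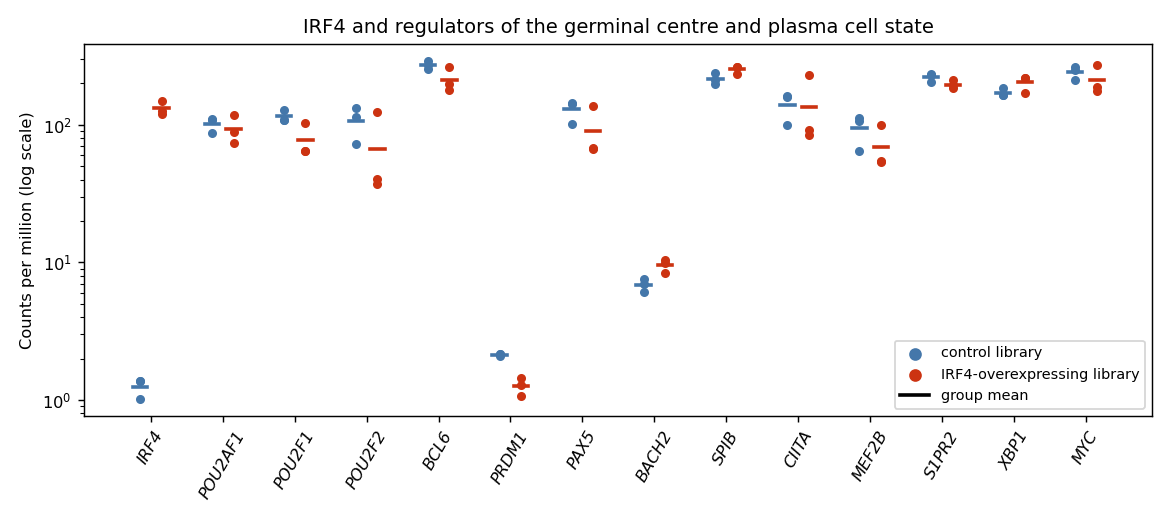
CPM on a log axis for IRF4 and 13 of the 14 study genes in each of the 3 control (blue) and 3 IRF4-overexpressing (red) libraries; horizontal lines are group means. The IRF4 groups are separated by 6.72 on the log2 scale.

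Among the falls, PTPRJ and PTPRC, which encode receptor tyrosine phosphatases, fell by 0.91 and 0.53 on the log2 scale (SE 0.11 and 0.09, edgeR adjusted p = 0.00953 and 0.0295). PAG1, an adaptor that holds Src-family kinases in check, fell by 0.61, and PRKCB, the kinase that links the B cell receptor to NF-kB, fell by 0.55. MAP2K6, NQO1, SLC16A6, SNX18, DNAJB1 and SLC12A8 fell by 0.50 to 0.84. With library sizes alone, NQO1, SNX18, DNAJB1 and SLC12A8 lost their calls (edgeR adjusted p = 0.0623, 0.0524, 0.0664 and 0.0834). DNAJB1 also lost it with median-ratio size factors, no filter and the stricter filter (edgeR adjusted p = 0.0513, 0.0679 and 0.0813). SLC12A8 lost it with no filter and with the offsets (edgeR adjusted p = 0.057 and 0.0665). Of the 12 largest falls, 11 lost the call without at least 1 library, and UBASH3B (-1.18, SE 0.10, edgeR adjusted p = 0.00223) passed without each library in turn. The 12 largest rises passed in all 6 such fits. These also held SHROOM3, an actin-binding protein gene (5.66-fold), and gene 100288255, which has no symbol in the tables used (20.7-fold).

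Genes of the amino acid stress response were lower as a list, with 2 of 17 fallen (3 adjusted over the list alone), ASNS, the asparagine synthetase gene, by 0.49 and CHAC1 by 0.79 on the log2 scale (camera adjusted p = 0.00391 preset, and 0.0965 with an estimated correlation). Both genes lost their calls in 5 of the 6 fits without a library, where 0 members passed, and with library sizes alone (edgeR adjusted p = 0.0572 and 0.0582), and CHAC1 also with median-ratio size factors, no filter and the stricter filter (edgeR adjusted p = 0.0526, 0.0531 and 0.0717). Without IRF4-overexpressing replicate 1, 7 members were lower and 1 higher. SESN2 and PHGDH had log2 fold changes of -0.62 and -0.82 and did not pass. The endoplasmic reticulum stress list was called lower (camera adjusted p = 2.47e-04 preset, and 0.114 with an estimated correlation) with 0 of 25 members passing edgeR's test, 10 lower at an unadjusted p under 0.05, 6 adjusted over the list alone, 6 by DESeq2 and 0 by limma-voom. Lower members numbered 16 without IRF4-overexpressing replicate 1 and 0 without any other library, 7 with the axis term, 14 with the surrogate variable and 4 with the offsets. Its members SDF2L1, PDIA4, PDIA3 and CALR, chaperones and folding enzymes, had log2 fold changes of -0.45, -0.39, -0.35 and -0.50. PDIA4, PDIA3 and CALR had means of 371, 372 and 903 CPM. The 2565 genes with a mean of 100 to 1000 CPM together summed to 0.919 of their control level. With TMM scaling, part of the falls of PDIA4, PDIA3 and CALR was thus shared by abundant genes as a class. With library sizes alone, that class summed to 0.982 of its control level. SDF2L1 had a mean of 17.0 CPM, and the genes of 10 to 30 CPM summed to 0.991 of their control level with TMM. The MYC and ribosome biogenesis list was called lower too (camera adjusted p = 0.00391 preset, and 0.164 with an estimated correlation). In it 0 of 25 passed by edgeR, DESeq2 or limma-voom, against 14 lower and 1 higher without IRF4-overexpressing replicate 1, 16 lower with the surrogate variable and 2 with the axis term. In the edgeR test 6 were lower at an unadjusted p under 0.05, among them PA2G4 (-0.30), DKC1 (-0.39), CDK4 (-0.25) and NOP16 (-0.26). The named genes also belong to the class of 100 to 1000 CPM. By fry, the amino acid stress, endoplasmic reticulum stress and MYC lists were called lower (fry adjusted p = 0.00134, 0.0045 and 0.0051).

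The other lists were not called. In the p53 list 4 of 23 rose (5 rose and 1 fell adjusted over the list alone; 0 to 8 and 0 to 4 without single libraries), including BBC3 and FAS, with a camera adjusted p of 0.0931; the list was called higher with the stricter filter (0.039), DESeq2 (0.0336) and limma-voom (0.0452), but not with the other scalings, no filter (0.162) or an estimated correlation (0.182). For S phase (RRM2 -0.66, RFC2 -0.30) it was 0.0545, and the list was called lower with median-ratio size factors (0.0444), no filter (0.0148), DESeq2 (0.0474) and limma-voom (0.0419), but not with library sizes alone (0.0773), the stricter filter (0.0765) or an estimated correlation (0.391). The camera adjusted p for glycolysis (ALDOA -0.41, PKM -0.41) was 0.165, and for G2 and M phase (CDC20 -0.32, KIF11 -0.31) 0.165. The G2 and M phase list was called lower with the axis term (0.0198), the surrogate variable (0.00364) and the offsets (0.0422), and glycolysis with the surrogate variable (0.041) and by fry (adjusted p = 0.00488). B cell identity genes had 0.221 (CXCR5 0.60, BANK1 -1.05), with 3 higher and 1 lower adjusted over the list alone. For cholesterol synthesis (HMGCS1 -0.53) it was 0.688, and for OXPHOS (COX5A -0.36, SDHC -0.40), ribosomal proteins (RPS21 -0.61, RPS2 -0.45) and replication histones (H2AC8 -0.45, H4C8 -0.33) 0.991. In these 8 lists after p53, 0 members passed edgeR's test, while 0 to 5 were higher and 2 to 7 lower at an unadjusted p under 0.05, and DESeq2 called 0 to 3 higher and 0 to 2 lower. Without IRF4-overexpressing replicate 1 edgeR called 1 to 25 higher and 2 to 13 lower, and without any other library 0. It called 0 to 5 higher and 2 to 14 lower with the surrogate variable, 0 to 3 and 0 to 4 with the axis term, and 0 to 2 and 0 to 3 with the offsets. Limma-voom called 1 higher and 1 lower in the B cell identity list and 0 in the other 7. The median was above 0 for cholesterol synthesis and OXPHOS (0.05 and 0.10) while their camera direction was down, and the ribosomal list had a median of 0.13 and a mean of -0.0011. Lists of immunoglobulin constant, mitochondrially encoded, T and NK, and epithelial, mesenchymal and kidney genes had 1, 0, 1 and 2 tested members and were not tested. Of the 46 genes that the naming rule gives and that did not pass, PRDM1 and CSF1R among them, 20 passed by DESeq2, 2 by limma-voom, 4 with library sizes alone, 12 with the offsets, 25 with the axis term, 39 with the surrogate variable, 45 without IRF4-overexpressing replicate 1 and 0 without any other library.

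**Figure D4:**
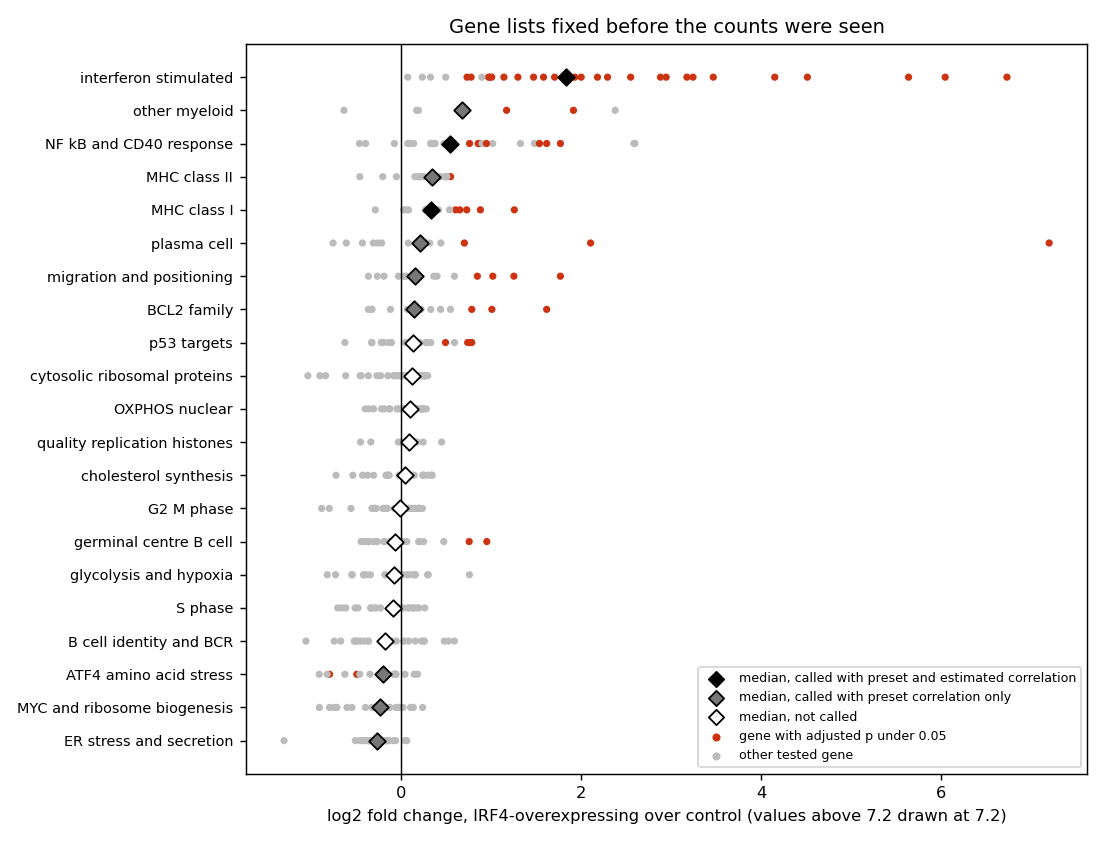
Log2 fold change of each tested gene (small points, red where the edgeR adjusted p was under 0.05) and the median (diamonds) of the 21 tested lists, sorted by median; black diamonds were called by camera with both correlations, grey ones with the preset correlation alone. The interferon list has the highest median, 1.84; the plasma cell point at 7.2 is CD28, cut off at that axis limit, whose fitted value of 8.99 depends on the prior count.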

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

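The sample axis term, the surrogate variable and the GC and length offsets were chosen after the data were examined; the other alternatives were planned. Over 20 alternatives, 1727 values kept their direction and side of the threshold or stayed within their limits, 191 lost their call, 169 gained one, 83 counts moved and 35 values changed sign. IRF4 stayed past the threshold in 16 of 16, at log2 fold changes of 6.58 to 6.83. Interferon members called higher numbered 23 to 30 in all but the replicate block fit. Depth and spread limit small changes: in simulated counts 9.1% of 1.5-fold changes were recovered.

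Leaving out each library gave 123 to 5507 changed genes (120 to 2436 higher, 3 to 3071 lower), 107 to 422 at least 2-fold higher and 3 to 661 at least 2-fold lower, 0 to 15 germinal centre, 1 to 15 plasma cell and 0 to 14 study genes, and 22 to 48 named genes. The upper ends came from leaving out IRF4-overexpressing replicate 1, which lies apart from replicates 2 and 3. These share an axis side with control replicate 1, opposite control replicates 2 and 3, so that fit mixes the group with the axis. Their own spread was also smaller. Fold changes moved too, as for POU2F2, with a log2 fold change of -1.46 in that fit and -0.67 with all libraries. Lists called without single libraries numbered 9 to 12. Library sizes alone gave 13 lower genes. DESeq2 gave 752 genes (577 higher, 175 lower, 11 at least 2-fold lower) and 2 study genes. glmTreat gave 144 (141 higher, 3 lower). The sample axis term gave 1098 (709 higher, 389 lower, 9 at least 2-fold lower), 4 germinal centre, 5 plasma cell and 3 study genes. The surrogate variable gave 3500 (1353, 2147 and 15), 12 germinal centre, 6 plasma cell and 8 study genes. GC and length offsets gave 684 (545 and 139) and 3 study genes. With an estimated correlation, 3 lists were called in place of 11. In the migration, myeloid, BCL2, plasma cell and amino acid stress lists, which lost the call, that correlation was below the preset 0.01. Correlation between members therefore does not explain the loss in these lists. Other causes were not tested. By fry, every list that lost its call with an estimated correlation was called in the same direction.

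The replicate number as a block left 3 genes (3 higher, 0 lower, 3 and 0 at least 2-fold; 1352 at an unadjusted p under 0.05), with 0 germinal centre, 0 plasma cell, 1 interferon and 0 study genes and 1 named gene besides IRF4. Same-numbered libraries correlated at -0.649, -0.219 and -0.467, and 0 of 3 matched its own number best, so the block does not join libraries that are alike. Replicate 1 differed most from the others in both groups, in opposite directions (chi-square per gene 35.6 and 55.6 against 6.6 between control replicates 2 and 3, and 182.3 and 199.9 against 8.1 in the IRF4-overexpressing group), which a shift shared by a number does not describe.

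None of the values that changed sign had passed the threshold in the fit reported. The gene CIITA had log2 fold changes of 0.0434 with library sizes alone, 0.18 with the axis term, 0.26 with the surrogate variable (edgeR adjusted p = 0.0045), 0.018 with GC and length offsets, and -0.6777 to 0.2198 without single libraries. The gene POU2AF1 had 0.00 with the axis term (6e-04), 0.0338 with the surrogate variable and -0.3395 to 0.0286 without single libraries. Of the 6 fits without a library, CIITA turned sign in 4 and POU2AF1 in 1. Lists changed direction at these adjusted p, from camera unless fry is named. OXPHOS turned at 0.971 (library sizes alone), 0.901 (stricter filter), 0.9 (limma-voom), 0.977 (block) and 0.939 (fry), and in 2 of the 6 fits without a library, whose p ran from 0.0567 to 0.784. Ribosomal proteins turned at 0.669 (no filter), 0.37 (axis term), 0.109 (surrogate variable) and 0.476 (offsets), and in 4 of those 6 fits, whose p ran from 0.0681 to 0.919. Histones turned at 0.712, 0.459, 0.222 and 0.343 for the same settings and 0.988 (DESeq2), and in 3 of those 6 fits, whose p ran from 0.0567 to 0.919. The germinal centre list turned at 0.939 (fry). The plasma cell list lost its call with the block (camera adjusted p = 0.0512). S phase was also called lower with the block, the axis term, the surrogate variable and the offsets (0.044, 0.013, 0.00472 and 0.038) and without control replicate 2 or 3 or IRF4-overexpressing replicate 2 or 3 (0.0301, 0.0263, 0.0188 and 0.0323). The p53 list was also called higher with the axis term (0.042), the surrogate variable (0.0102) and fry (5.35e-04). The cause was not tested.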

Other observations

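Other genes outside the fixed lists rose in the IRF4-overexpressing libraries; these were chosen after their values were seen. The guanylate-binding protein genes GBP1 and GBP4 had log2 fold changes of 2.54 and 2.83 (edgeR adjusted p = 8.94e-04 and 5.38e-04), reaching 4.59 ± 0.428 and 3.74 ± 0.198 CPM (SD, n = 3). CXCL11, a partner of CXCL9 and CXCL10 at the receptor CXCR3, had 2.93, and TLR7, a sensor of single-stranded RNA, 2.86 (edgeR adjusted p = 0.00794 and 0.00127). The B cell activation genes SLAMF1, RGS1 and TNFRSF9 had 2.03, 2.30 and 1.52, and the adhesion gene VCAM1 had 1.37 (SE 0.19, 0.20, 0.13 and 0.14). In each of these genes, every IRF4-overexpressing library lay above every control library, while chance separates 3 libraries from 3, in either direction, for 10% of genes.

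All tests of the interferon and weak-gene patterns, and that of replicate numbers, were chosen after the result was seen, and the full marker lists replaced the 17 abundant markers after these had been read; the tests of splits, GC content and depth on the library axis were set before. There are 10 splits of the 6 libraries into 3 and 3, too few for a share under 0.05. The real split gave 382 changed genes and the highest other 2896, with 2 of the 10 at or above the real value, and 253 against 363 at least 2-fold, again 2. The real split called 11 lists and the highest other 10, so 1 split reached the real value. Every other split called at least 4 lists, also where 0 genes changed. A list call with the preset correlation alone therefore does not single out the real groups. For germinal centre, plasma cell and study genes the real split gave 2, 3 and 1 and the highest other 5, 8 and 7, with 2 splits each at or above. For interferon genes it gave 27 against 0, and 1 split reached that. The split with 2896 genes is the library axis, a structure of the samples.

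The interferon rise was weighed first. With the axis as a term the median log2 fold change of all 32 tested genes was 1.764, against 1.839 without it (SD of the change per gene 0.096), which argues against the axis as its cause. The 58 markers of myeloid, T and NK, epithelial, mesenchymal and kidney cells summed to 8.59 CPM more (65.5 ± 4.66 and 74.1 ± 5.07 CPM, SD, n = 3 each). The 17 abundant ones, which leave out ITGAM, MS4A7 and CSF1R, summed to 0.202 CPM more. The 32 interferon genes summed to 980.8 CPM more, which argues against cells of these types as the cause of their rise. The markers do not cover B cells of another origin, so such cells were not examined and stay open. Of the 22 genes in the table that encode interferons, 18 had 0 counts in every library, and IFNG, IFNL4 and IFNL2 had 1, 0 and 0 in control and 4, 3 and 1 in IRF4-overexpressing libraries; IFNB1, encoding interferon beta and picked from these after its counts were seen, had 0, 0 and 2 counts in control and 9, 13 and 8 in IRF4-overexpressing libraries, a ratio of 13 (95% counting interval 3.29 to 112), above the ratio of 1.60 of weak genes as a class, so interferon made by the cells may take part. Direct action of IRF4 on these genes and a reaction to the insert stay open, as untested. Control cells received the vector without insert, so a reaction to the vector alone would be shared by both groups. A difference in virus dose between the groups was not examined and stays open too.

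Weakly expressed genes were higher in the IRF4-overexpressing libraries: the 5429 genes with a mean of at most 0.3 CPM summed to 231 ± 9.06 CPM in control and 370.1 ± 10.7 CPM in IRF4-overexpressing libraries (SD, n = 3 each), a ratio of 1.60, and 169 of the 360 higher genes had a mean of at most 3 CPM. Depth and scaling are argued against, by a gap of 639 detected genes after thinning to 27681979 counts and a ratio of 1.712 with library sizes alone. Background was tested in a pair of ways: reads of olfactory, taste and vomeronasal receptor, keratin-associated and defensin genes, which B cells do not use, rose 1.75-fold (interval 1.46 to 2.1), as background would give. That ratio rests on 50 genes with reads, themselves part of the weak class. Of the 518 coding genes of these families, 467 had no read in any library. The ratio therefore does not separate background from a rise of the few genes with reads. A second test was added after the 1.75-fold rise was known. In these libraries 4335 weak coding genes had no read. If the whole rise were spread evenly over bases, 2297 ± 35 (SD) would be expected. This argues against an even background as the whole cause, but not against one as a part. Uneven background, an even background as a part, and a true rise of many weak genes may all contribute and stay open.

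The library axis was weighed last. Across genes, the fold change along the axis correlated with GC content and gene length (rho 0.374 and 0.285). Removing both trends left 85.2% of the group-centred sum of squares. The first component held 72.8% of the variance that remained, against 74.3% before removal. After thinning to equal depth it held 73.5%. These values argue against GC content, length and depth as the whole cause of the axis. Replicate 1 lay apart from replicates 2 and 3 in both groups, in opposite directions, so for 0 of the 3 replicate numbers did both libraries lie on the same side. With unequal sides all 3 could not have agreed, so this count excludes nothing. Around the group means, same-numbered libraries correlated at -0.649, -0.219 and -0.467. A shift shared by a number would move both its libraries alike, so these correlations argue against it as the whole cause. A batch or culture difference of another kind stays open, and no biological explanation was tested.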
